A study of Mus musculus with 85 samples.

How the data were processed

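The series holds 85 samples: 64 RNA sequencing libraries in 20 groups and 21 chromatin immunoprecipitation samples (H4K16ac, pan-H3 and input in neural cells), which are not analysed here. Per the labels, RNA came from mouse embryos at E14.5, from whole brain and from sorted neural cells, endothelial cells, pericytes and microglia, with neural knockouts (nKO) of Mof, Kansl2 or Kansl3 and Cre controls. Microglia were profiled for Mof alone. A further set holds primary adult-brain pericytes in culture with fatty acids or vehicle (ethanol with bovine serum albumin). Per the labels, whole-brain, neural and cultured pericyte libraries were made with TruSeq, and sorted endothelial, pericyte and microglial libraries with SMART-Seq v4 and Nextera XT. A pair of Illumina sequencers (HiSeq and NextSeq) is named, and which sample ran on which is not stated.

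Per the submitters' processing notes, reads were mapped to mm10 with STAR and counted with featureCounts, and differential expression was run with DESeq2; versions are not given in the sources used here. The deposited tables of whole brain and cultured pericytes hold counts, the raw reads per Ensembl gene. The sorted-cell tables hold a signal that the authors made by dividing gene counts by a size factor for each library within each table. The authors' deposited tables also give log2 fold changes (unit log2) and an adjusted p-value per gene (unit p_value). Those of whole brain carry the columns of an edgeR test and the others those of a DESeq2 Wald test. Dividing each library by its value of a single read gave back whole reads for 100% of values in 68 library columns, within a tolerance of 0.01. These recovered reads were used for depth and for alternatives.

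Reads per library ran from 8444551 to 12641817 in whole brain, 5687012 to 12665665 in neural cells, 10048082 to 25260285 in endothelial cells, 1572515 to 5852542 in pericytes, 2215701 to 9817084 in microglia and 42623429 to 51854152 in cultures. No pair of libraries within a group was a duplicate among 72 pairs compared. The labels do not say that libraries come from separate animals beyond the sample names; if they do not, p-values then measure only the spread between these samples. An endothelial column named M436 matched no sample title, while a title M432 matched no column, so that library was placed by its group alone. Libraries are called by the last part of their titles (K2 and K3 stand for Kansl2 and Kansl3). The names M643, M646 and M689 occur in neural cells and in microglia. Gene symbols came from the authors' tables: of 43626 whole-brain features 41333 took one from their own table, 1755 from another table and 538 had none.

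Comparisons, gene lists and alternatives were fixed before the data were examined. There were 14 comparisons against Cre or vehicle, and 3 of whole-brain knockouts with each other. Raw counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), with all 12 whole-brain libraries in 1 fit. Sorted-cell signals were tested with limma 3.58.1 (trend) on log2(value + 1) for genes with a mean of at least 10; this scale understates folds of low genes. The p-values were adjusted by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05. The SE of an edgeR fold change is its size divided by the square root of F. "Rose" and "fell" mark what passed. DESeq2 1.42.0 served for alternatives. R was 4.3.3, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

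The 30 lists were the NSL complex, MSL complex, fatty acid oxidation, fatty acid synthesis and elongation, cholesterol synthesis, PPAR targets, respiratory chain, glycolysis, hypoxia response, p53 targets, integrated stress response, unfolded protein response, Toll-like receptor and NF-kB response, interferon response, extracellular matrix, contractile genes, blood-brain barrier, angiogenesis, homeostatic microglia, activated microglia, cell cycle, and markers of neural progenitors, neurons, endothelial cells, pericytes, microglia and macrophages, erythroid cells, fibroblasts, neutrophils and monocytes, and choroid plexus. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The estimated setting also uses fewer degrees of freedom, so its p-values can be larger even where the estimate is low.

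Genes were named by rule. Kat8, Kansl2 and Kansl3 were named in every knockout comparison. The 5 largest rises and falls were named among genes that passed, had a mean normalized value of at least 50 and had groups that did not overlap, without sex-linked genes (Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d, Uty), predicted genes and genes with no symbol. Up to 4 members with the smallest p were named per list, of those that passed where any did. The text names some of these, and some are not reported here.

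Alternatives for raw counts were relative log size factors, DESeq2, no filter, only the 6 libraries compared, a replicate block in cultures, and each library left out. For sorted cells they were a pseudocount of 8, a mean of at least 1 or 50, TMM on the deposited values, edgeR and DESeq2 on recovered reads, and each library left out. Chosen after seeing the data were array weights in endothelial cells, pericytes and microglia, microglia without M646 and M689, and edgeR without Cre130 in endothelial cells. The pipeline was tested on simulated data with 200 changed genes, all with a mean of at least 50 reads. At 2-fold it found 94.0%, 94.0% and 98.5% in whole brain for Mof, Kansl2 and Kansl3, and 98.5%, 100.0% and 97.0% in neural cells. It found 1.49%, 0 and 2.99% in endothelial cells, 25.4%, 38.8% and 40.3% in pericytes, 0 in microglia and 91.0% in cultures. Recovery of lower genes was not simulated. Of 20 random lists 0 were called, but simulated genes were drawn independently, so this does not test lists of correlated genes.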

Results

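What changes in the embryonic brain when subunits of the NSL complex are deleted from neural cells? The NSL complex is a histone acetyltransferase assembly built around MOF, the enzyme encoded by Kat8, with KANSL2 and KANSL3 among its partner subunits. Neural knockouts (nKO, by Nestin-Cre) of Mof, Kansl2 or Kansl3 were compared with Cre controls at E14.5, in whole brain and in sorted neural, endothelial, pericyte and microglial cells. Cultured pericytes were compared with and without fatty acids. The 64 RNA libraries form 20 groups of 3 or 4, with 1572515 reads in the smallest library (sorted pericytes) and 51854152 in the largest (culture).

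Kat8 counts fell in all 6 comparisons of whole brain and neural cells. In whole brain Kat8 fell from 201 ± 29.2 normalized counts in Cre controls to 105 ± 7.88 in Mof nKO (mean ± SD, n = 3 per group), a log2 fold change of -0.94 ± 0.13 (± SE, adjusted p = 0.00234). It also fell to 129 ± 7.16 in libraries labelled Kansl2 nKO (-0.64 ± 0.13, adjusted p = 0.0027) and to 108 ± 7.04 in those labelled Kansl3 nKO (-0.89 ± 0.14, adjusted p = 0.000317). In neural cells Kat8 fell by 1.42 ± 0.12 on the log2 scale under Mof (adjusted p = 9.34e-08), by 0.57 ± 0.11 under the Kansl2 label (adjusted p = 0.00083) and by 1.16 ± 0.11 under the Kansl3 label (adjusted p = 1.01e-06; n = 3 per group). Kansl2 and Kansl3 were not lower in the libraries named for them. Whole brains labelled Kansl2 nKO held 451 ± 25.8 Kansl2 counts against 328.3 ± 25.8 in Cre controls (0.46 ± 0.10, adjusted p = 0.00357). Those labelled Kansl3 nKO held 901 ± 28.1 Kansl3 counts against 744 ± 29.6 (0.28 ± 0.11, adjusted p = 0.0602). In neural cells the Kansl2 value under the Kansl2 label was 0.09 ± 0.09 (adjusted p = 0.491), and Kansl3 rose by 0.28 ± 0.07 under the Kansl3 label (adjusted p = 0.00542).

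Since these totals go against the labels, the groups are called "labelled Kansl2 nKO" and "labelled Kansl3 nKO" throughout, and every direction given for them rests on the labels. A gene total can miss a deletion that leaves most of the transcript in place. In sorted endothelial cells, pericytes and microglia, none of Kat8, Kansl2 and Kansl3 passed the test in any comparison. Kat8 under Mof stood at -0.30 ± 0.41 in endothelial cells (adjusted p = 0.84, n = 4 per group), -0.18 ± 0.48 in pericytes (adjusted p = 0.9, n = 3 against 4) and -2.19 ± 1.82 in microglia (adjusted p = 0.718, n = 3 per group).

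**Figure D1:**
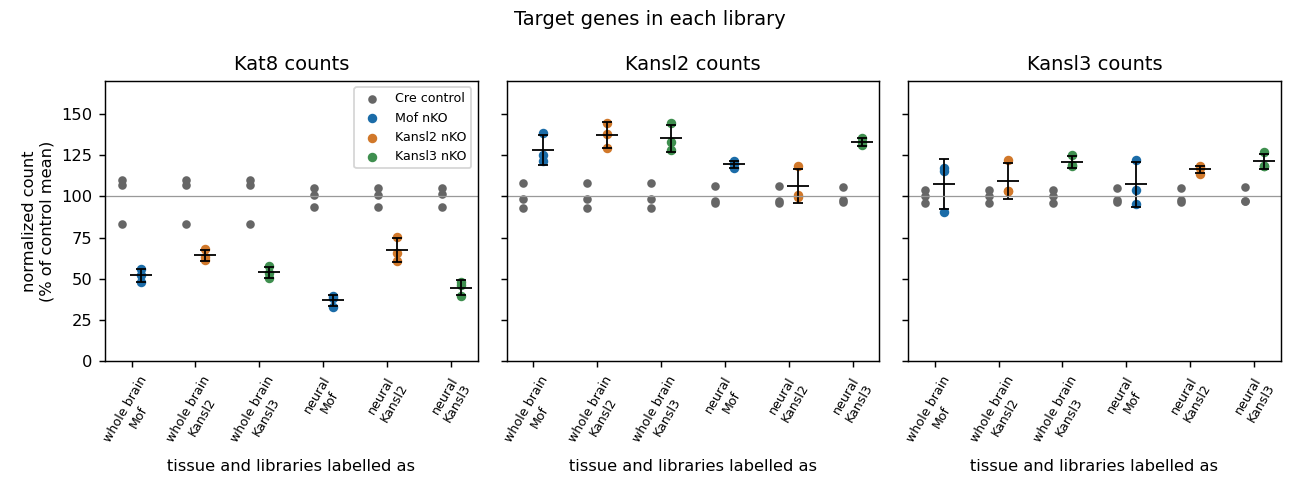
Normalized counts of Kat8, Kansl2 and Kansl3 in percent of the control mean (vertical axis) for whole brain and neural cells of each labelled knockout (horizontal axis); each point is a library, bars are mean ± SD of the knockout libraries (n = 3), grey points are Cre controls. Kat8 means lie below the control mean in all 6 comparisons, while Kansl2 and Kansl3 means lie above it.

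In whole brains of Mof nKO 314 genes rose and 658 fell among 16290 tested with edgeR (n = 3 per group). Spp1, a secreted glycoprotein made by activated microglia, rose from 9.86 ± 6.13 to 123 ± 21.3 counts (log2 fold change 3.62 ± 0.32, adjusted p = 5.29e-05). The p53 target Eda2r rose from 22.7 ± 9.07 to 233 ± 40.4 (3.37 ± 0.25, adjusted p = 1.72e-05). Sesn2, a stress-induced sestrin, rose from 61.5 ± 4.62 to 233 ± 35.5 (1.92 ± 0.16, adjusted p = 3.5e-05). Neb, the muscle thin-filament gene nebulin, fell from 188 ± 10.2 to 40.0 ± 7.98 (-2.23 ± 0.18, adjusted p = 3.5e-05). Aldh1l1, a folate enzyme of the astroglial lineage, fell from 341 ± 35.3 to 114 ± 14.8 (-1.58 ± 0.20, adjusted p = 0.000948). Pdgfra, the receptor of oligodendrocyte precursors, fell by 2.23 ± 0.54 on the log2 scale (adjusted p = 0.0307).

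Of 23 p53 targets 10 rose (16 when adjusted over the list alone), among them Phlda3 (1.89 ± 0.18), Aen (1.13 ± 0.13) and Ccng1 (0.95 ± 0.11). As a list they ranked above other genes (camera adjusted p = 7.76e-11; adjusted p = 0.0714 with an estimated correlation). The integrated stress response, the program driven by ATF4 that raises amino acid supply genes, had 7 of 19 members up (11 adjusted over the list alone), with Atf4 at 0.64 ± 0.09 and Atf3 at 3.10 ± 0.44 (camera adjusted p = 2.54e-09, adjusted p = 0.124 with an estimated correlation). Activated microglia genes (6 of 16 up, 10 adjusted over the list alone) included Gpnmb (3.87 ± 0.58) and Clec7a (4.10 ± 0.73), with camera adjusted p = 2.39e-09 and adjusted p = 0.0714 with an estimated correlation. Among microglia and macrophage markers 5 of 10 rose (7 adjusted over the list alone), with Tyrobp at 2.17 ± 0.25 and C1qb at 1.57 ± 0.20 (camera adjusted p = 2.39e-09, adjusted p = 0.0714 with an estimated correlation). Their share of reads was 0.00568 ± 0.000543% against 0.00298 ± 0.000243% in Cre controls. Erythroid markers held 0.0726 ± 0.0325% against 0.0416 ± 0.00265%, with no overlap between groups; all 10 stood above 0 and none passed (median 0.74, camera adjusted p = 0.00581, adjusted p = 0.776 with an estimated correlation). Fatty acid oxidation genes had 7 of 27 members down (16 adjusted over the list alone), including Acadvl, which starts long-chain oxidation (-0.71 ± 0.14), Decr1 (-0.92 ± 0.19) and Hsd17b4 (-0.64 ± 0.15). This list ranked low with camera adjusted p = 6e-08, and with adjusted p = 0.145 with an estimated correlation. The count of changed genes leaned on single libraries: it was 170 without Mof_197, 194 without Mof_193, and 233, 253 and 304 without Cre_19, Cre_18 and Cre_16. With no filter on low counts it was 1636, of which 52.7% rose.

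In whole brains labelled Kansl2 nKO, microglia genes and p53 targets rose. Gpnmb, a lysosomal glycoprotein of activated microglia, rose from 2.03 ± 2.25 to 239 ± 66.7 counts (log2 fold change 6.77 ± 0.45, adjusted p = 5.21e-07). Spp1 rose to 1014 ± 131 (6.67 ± 0.29, adjusted p = 1.07e-08). Lyz2, the lysozyme of myeloid cells, rose from 11.01 ± 2.66 to 214 ± 18.4 (4.27 ± 0.33). C3ar1, a complement receptor, rose by 3.77 ± 0.30, and Eda2r rose to 492 ± 58.3 (4.45 ± 0.24, adjusted p = 5.41e-08). Neb fell to 25.1 ± 0.696 (-2.89 ± 0.20, adjusted p = 6.76e-07). Cyp4f16, a fatty acid hydroxylase family member, fell from 133.8 ± 8.71 to 22.6 ± 4.68 (-2.52 ± 0.22). Metap1d, a mitochondrial methionine aminopeptidase, fell from 306 ± 49.6 to 69.5 ± 17.7 (-2.14 ± 0.21). With edgeR 1688 genes rose and 2644 fell among 16290 (n = 3 per group).

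Of 23 p53 targets 20 rose, including Phlda3 (3.34 ± 0.17), Ccng1 (1.99 ± 0.11) and the cell cycle inhibitor Cdkn1a (2.77 ± 0.19). The list passed under either correlation (camera adjusted p = 2.09e-15, adjusted p = 0.0397 with an estimated correlation). So did activated microglia genes (13 of 16 up, camera adjusted p = 7.46e-13, adjusted p = 0.0397 with an estimated correlation), with Apoe at 2.24 ± 0.20 and Lgals3 at 4.46 ± 0.49. The integrated stress response had 14 of 19 members up (15 adjusted over the list alone), with Sesn2 at 3.40 ± 0.16, Asns, which makes asparagine, at 1.16 ± 0.11 and Chac1 at 2.11 ± 0.22 (camera adjusted p = 1.68e-11, adjusted p = 0.0711 with an estimated correlation). Microglia and macrophage markers had 9 of 10 up, with the complement genes C1qa at 2.85 ± 0.22 and C1qb at 2.67 ± 0.19 (camera adjusted p = 2.03e-10, adjusted p = 0.0547 with an estimated correlation). Homeostatic microglia genes had 6 of 10 up, with Fcrls at 2.32 ± 0.18 (camera adjusted p = 0.000227, adjusted p = 0.243 with an estimated correlation). Of 27 fatty acid oxidation genes 11 fell, with Acox3 at -1.11 ± 0.12 and the carnitine carrier Slc25a20 at -1.35 ± 0.19 (camera adjusted p = 0.00306, adjusted p = 0.601 with an estimated correlation). Of 56 respiratory chain genes 13 fell (10 adjusted over the list alone), with Ndufs8 at -1.04 ± 0.18 and Ndufv1 at -0.76 ± 0.14 (camera adjusted p = 0.000288, adjusted p = 0.601 with an estimated correlation). Of 10 erythroid markers 5 rose (7 adjusted over the list alone), with Hba-a2 at 1.47 ± 0.40 (camera adjusted p = 0.00306, adjusted p = 0.601 with an estimated correlation). Without Cre_16 the count of changed genes was 2843.

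Whole brains labelled Kansl3 nKO had the most changed genes of the 3 whole-brain comparisons. Gpnmb rose to 244 ± 74.4 counts (6.79 ± 0.45, adjusted p = 5.04e-07), Spp1 to 961 ± 236 (6.59 ± 0.29, adjusted p = 1.28e-08) and Lyz2 to 222 ± 107 (4.32 ± 0.33), while Eda2r rose by 4.26 ± 0.24. Neb fell to 29.2 ± 7.24 (-2.69 ± 0.19). Dhrs1, a dehydrogenase/reductase, fell from 241 ± 3.74 to 60.7 ± 8.93 (-1.99 ± 0.15, adjusted p = 1.81e-06). Poll, a DNA repair polymerase, fell by 1.92 ± 0.22 on the log2 scale. With edgeR 2478 genes rose and 3065 fell among 16290 (n = 3 per group).

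In this group, of 56 respiratory chain genes 32 fell (36 adjusted over the list alone) and none rose, with Ndufv1 at -1.19 ± 0.15 and Ndufa10 at -0.77 ± 0.13 (camera adjusted p = 2.41e-08, adjusted p = 0.501 with an estimated correlation). Cholesterol synthesis genes had 12 of 22 members down (14 adjusted over the list alone), with Nsdhl at -0.79 ± 0.12 and Lss at -0.52 ± 0.09 (camera adjusted p = 1.61e-05, adjusted p = 0.341 with an estimated correlation). Fatty acid oxidation genes had 13 of 27 down and 1 up (15 down adjusted over the list alone), with Cpt2, the inner-membrane carnitine palmitoyltransferase, at -1.94 ± 0.31 and Slc25a20 at -1.17 ± 0.19 (camera adjusted p = 0.000856, adjusted p = 0.41 with an estimated correlation). Fatty acid synthesis and elongation genes went both ways (2 up, 8 down of 29, camera adjusted p = 0.372), with the desaturases Scd1 at -1.07 ± 0.14 and Scd2 at -0.87 ± 0.11. Neural progenitor markers had 7 of 14 down (9 adjusted over the list alone), with Sox2 at -0.83 ± 0.15 (camera adjusted p = 0.00679, adjusted p = 0.501 with an estimated correlation). Of 23 p53 targets 17 rose (18 adjusted over the list alone; camera adjusted p = 5.75e-11, adjusted p = 0.0675 with an estimated correlation). Among activated microglia genes 13 of 16 rose (camera adjusted p = 7.3e-11, adjusted p = 0.0675 with an estimated correlation), with Trem2 at 2.50 ± 0.26. Erythroid markers had 8 of 10 up and Hbb-bs at 1.37 ± 0.36 (camera adjusted p = 0.000856, adjusted p = 0.501 with an estimated correlation). The count of changed genes was 3638 without Cre_16 and 3664 without K3_149.

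How similar were the whole-brain knockouts to each other? All 3 comparisons used the same 3 Cre libraries, which alone raises agreement, so each value stands beside 20 simulations of unchanged groups against shared controls. Across 16290 genes, which are not independent replicates, log2 fold changes correlated at r = 0.714 for Mof with Kansl2 (simulated 0.480), 0.727 for Mof with Kansl3 (simulated 0.476) and 0.844 for Kansl2 with Kansl3 (simulated 0.475). Kansl2 and Kansl3 shared 1170 higher and 2045 lower genes, where the sizes of the lists alone give 257 and 497, with a covariance of 0.346 against 0.0350 simulated. Tested directly, 1409 genes differed between Mof nKO and the libraries labelled Kansl2 nKO, 2196 between Mof and Kansl3, and 6 between Kansl2 and Kansl3. The first count was 439 and 844 without K2_63 and K2_70, and 725 and 505 without Mof_193 and Mof_197. The second was 1243, 1297 and 702 without K3_117, K3_119 and K3_149, and 1389 and 1050 without Mof_197 and Mof_200. The 6 genes became 1041 without K2_68, the only library of these groups with Xist above Ddx3y. They became 2 without any one of K2_63, K2_70 or K3_119, and 11 without K3_149. K2_63 stood apart in its group, with 9.88% mitochondrial reads against 22.4% in K2_68 and 19.8% in K2_70. Its counts differed from theirs by a chi-square per gene of 70.5 and 45.7, against 9.54 between K2_68 and K2_70. Whether sex or K2_63 moved the count was not tested. Between Kansl2 and Kansl3, 2938 of 16290 genes had an unadjusted p under 0.05, where chance gives 5%. Cholesterol synthesis, cell cycle and respiratory chain genes stood higher under Kansl2 than under Kansl3 as lists, with medians of 0.28, 0.34 and 0.23 (camera adjusted p = 4.34e-06, 1.68e-05 and 7.83e-05, and adjusted p = 0.61 with an estimated correlation for each). Neural progenitor and endothelial markers stood higher with them, with medians of 0.28 and 0.36 (camera adjusted p = 0.000939 and 0.00376), as did the integrated stress response, p53 targets and angiogenesis genes at 0.27, 0.19 and 0.26 (camera adjusted p = 0.000784, 0.00259 and 0.00259). For each of these, adjusted p = 0.61 with an estimated correlation.

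**Figure D2:**
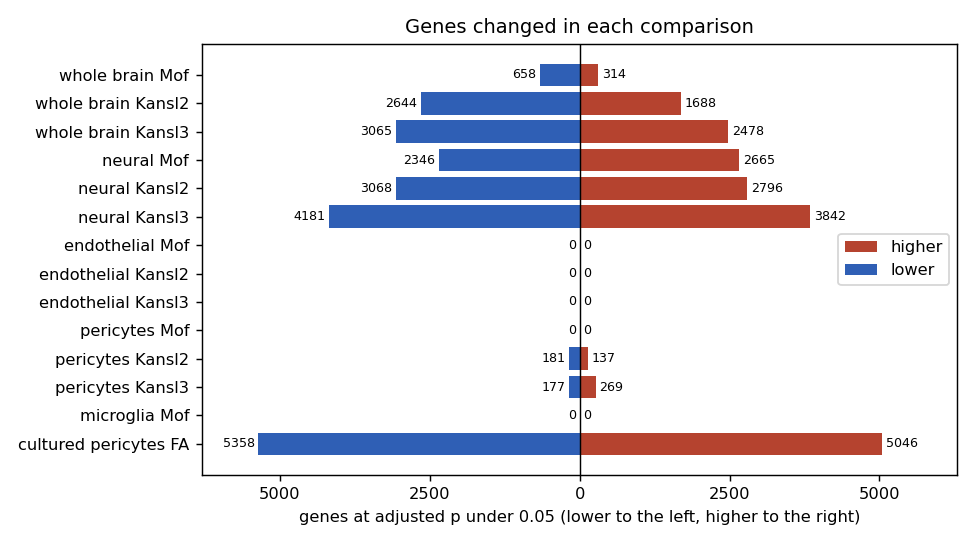
Number of genes at adjusted p under 0.05 in each comparison (horizontal axis, genes; lower to the left, higher to the right), by comparison (vertical axis); bars are counts against the Cre or vehicle control. Counts run from 0 in endothelial cells, Mof pericytes and microglia to 5046 higher and 5358 lower in cultured pericytes given fatty acids.

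In sorted neural cells microglia and macrophage markers averaged at most 0.000107% of reads in any group. In those of Mof nKO, Eda2r rose from 42.2 ± 4.29 to 296.4 ± 41.3 normalized counts (log2 fold change 2.78 ± 0.14 on the log2(value + 1) scale, adjusted p = 1.36e-10). Sesn2 rose by 1.77 ± 0.11, Phlda3 by 1.72 ± 0.18 and Chac1 by 1.62 ± 0.19. Sp9, a transcription factor of striatal and cortical interneurons, fell from 388 ± 5.51 to 88.5 ± 4.82 (-2.12 ± 0.10, adjusted p = 1.06e-10) and Dlx2 from 213 ± 9.91 to 59.6 ± 12.4 (-1.84 ± 0.15). Slc18a2, the vesicular monoamine transporter, fell from 251 ± 22.2 to 71.3 ± 2.62 (-1.80 ± 0.12). Neb fell by 2.57 ± 0.21 on the log2 scale. With limma 2665 genes rose and 2346 fell among 13724 (n = 3 per group).

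Of 17 integrated stress response genes 14 rose, with Slc7a5, an amino acid transporter, at 1.21 ± 0.09, Asns at 1.16 ± 0.11 and Atf4 at 0.55 ± 0.06. The list passed under either correlation (camera adjusted p = 7.48e-11, adjusted p = 0.0392 with an estimated correlation). Among 20 p53 targets 15 rose (16 adjusted over the list alone, with 1 down), including Aen at 1.27 ± 0.09 and Ccng1 at 1.11 ± 0.09 (camera adjusted p = 1.09e-08, adjusted p = 0.126 with an estimated correlation). Cell cycle genes had 21 of 25 members up (22 adjusted over the list alone), with the replication genes Mcm6 at 0.54 ± 0.06 and Pcna at 0.49 ± 0.06 (camera adjusted p = 7.48e-11, adjusted p = 0.204 with an estimated correlation). Neural progenitor markers had 7 of 14 up at the same time, with Pax6 at 0.60 ± 0.07 and Vim at 0.44 ± 0.06 (camera adjusted p = 0.00051, adjusted p = 0.204 with an estimated correlation), while Gad1 and Gad2 of inhibitory neurons fell by 0.66 ± 0.07 and 0.61 ± 0.07. Respiratory chain genes had 34 of 56 down and 1 up (37 down adjusted over the list alone), with Ndufs8 at -0.76 ± 0.10 and Ndufs6 at -0.98 ± 0.15 (camera adjusted p = 2.75e-09, adjusted p = 0.204 with an estimated correlation). Fatty acid oxidation genes had 13 of 27 down and 2 up (14 down adjusted over the list alone), with Slc25a20 at -0.92 ± 0.14 and Decr1 at -1.13 ± 0.19 (camera adjusted p = 0.00164, adjusted p = 0.126 with an estimated correlation). Glycolysis genes had 11 of 17 up and 3 down, with Eno1 at 0.53 ± 0.07 and Tpi1 at 0.48 ± 0.06 (camera adjusted p = 0.00627, adjusted p = 0.204 with an estimated correlation). Erythroid markers had 6 of 9 up, with Hba-a1 at 0.92 ± 0.10 (camera adjusted p = 0.00233, adjusted p = 0.204 with an estimated correlation).

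In neural cells labelled Kansl2 nKO, Eda2r rose from 44.9 ± 4.56 to 411 ± 29.5 (3.17 ± 0.13, adjusted p = 2.12e-10), Cdkn1a from 16.02 ± 4.67 to 95.5 ± 20.47 (2.52 ± 0.25) and Sesn2 from 100.1 ± 6.63 to 578 ± 42.0 (2.52 ± 0.11, adjusted p = 2.12e-10). Neb fell from 131 ± 20.6 to 14.8 ± 4.49 (-3.09 ± 0.23). Cyp4f16 fell by 2.08 ± 0.18 on the log2 scale, and Dlx1as, an antisense transcript at the Dlx1 locus, fell by 1.96 ± 0.15. The zinc finger genes Zfp85 (-2.16 ± 0.31) and Zfp772 (-1.96 ± 0.20) fell as well. Of 17 integrated stress response genes 16 rose, with Asns at 1.76 ± 0.10. Of 21 p53 targets 17 rose (18 adjusted over the list alone), with Ccng1 at 1.73 ± 0.08 (camera adjusted p = 1.15e-11 and 1.22e-10, and adjusted p = 0.117 with an estimated correlation for both). Cell cycle genes had 24 of 25 up (25 adjusted over the list alone), with Top2a at 0.56 ± 0.07 (camera adjusted p = 1.23e-11, adjusted p = 0.163 with an estimated correlation). Neural progenitor markers had 8 of 14 up at the same time, with Nes at 0.81 ± 0.09 (camera adjusted p = 0.00179, adjusted p = 0.266 with an estimated correlation). Respiratory chain genes had 35 of 56 down, with Ndufv1 at -0.85 ± 0.08 (camera adjusted p = 7.69e-08, adjusted p = 0.266 with an estimated correlation). Fatty acid oxidation genes had 14 of 27 down and 2 up (15 down adjusted over the list alone), with Slc25a20 at -1.88 ± 0.14 and Acox3 at -1.53 ± 0.15 (camera adjusted p = 0.00232, adjusted p = 0.117 with an estimated correlation). The unfolded protein response, which expands folding capacity of the endoplasmic reticulum, had 9 of 16 up and 2 down (10 up adjusted over the list alone), with Hspa5 at 0.53 ± 0.07 (camera adjusted p = 0.00246, adjusted p = 0.369 with an estimated correlation). Erythroid markers had 7 of 10 up (8 adjusted over the list alone), with Hba-a2 at 0.56 ± 0.13 (camera adjusted p = 0.00179, adjusted p = 0.266 with an estimated correlation). With limma 2796 genes rose and 3068 fell among 13903 (n = 3 per group).

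In neural cells labelled Kansl3 nKO the counts reached 3842 genes up and 4181 down among 14534 (limma, n = 3 per group). Eda2r rose from 55.3 ± 5.52 to 798 ± 142.1 (3.82 ± 0.13, adjusted p = 1.75e-10), Cdkn1a from 19.8 ± 5.82 to 215 ± 41.4 (3.40 ± 0.22). Slc7a3, a cationic amino acid transporter, rose from 11.8 ± 4.56 to 100.3 ± 19.5 (3.02 ± 0.27). Dpp7, a lysosomal dipeptidase, fell from 259 ± 6.91 to 37.5 ± 4.31 (-2.76 ± 0.14, adjusted p = 1.12e-08). Msrb1, a methionine sulfoxide reductase, fell by 2.69 ± 0.19 on the log2 scale and Metap1d by 2.66 ± 0.16. Respiratory chain genes had 52 of 56 members down and none up (53 down and 1 up adjusted over the list alone), with Ndufs8 at -1.66 ± 0.10, Ndufv1 at -1.52 ± 0.10 and Ndufv3 at -1.16 ± 0.11 (camera adjusted p = 3.55e-14, adjusted p = 0.346 with an estimated correlation). Of 22 p53 targets 19 rose (19 up and 1 down adjusted over the list alone), with Zmat3 at 2.07 ± 0.10. Of 18 integrated stress response genes 15 rose, with Slc7a5 at 1.73 ± 0.09 (camera adjusted p = 1.39e-09 and 3.4e-08, and adjusted p = 0.226 with an estimated correlation for both). Extracellular matrix genes had 15 of 22 up, with the basement membrane genes Hspg2 at 1.63 ± 0.11 and Lamc1 at 0.91 ± 0.10 (camera adjusted p = 1.04e-05, adjusted p = 0.246 with an estimated correlation). Toll-like receptor and NF-kB genes, the innate immune signaling list, had 7 of 11 up, with the feedback inhibitors Tnfaip3 at 1.80 ± 0.15 and Nfkbia at 1.11 ± 0.11 (camera adjusted p = 0.00414, adjusted p = 0.226 with an estimated correlation). Fatty acid oxidation genes had 14 of 27 down and 4 up, with Slc25a20 at -2.10 ± 0.14 (camera adjusted p = 0.0256, adjusted p = 0.38 with an estimated correlation). All 9 erythroid markers rose, with Hba-a2 at 1.16 ± 0.19 (camera adjusted p = 0.000448, adjusted p = 0.346 with an estimated correlation), and they held 0.144 ± 0.0578% of reads against 0.0566 ± 0.0104% in Cre controls.

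Neural fold changes, with shared Cre animals again, correlated across genes at r = 0.756 for Mof with Kansl2 (simulated 0.496), 0.649 for Mof with Kansl3 (simulated 0.501) and 0.818 for Kansl2 with Kansl3 (simulated 0.502). In the last pair 1903 genes were higher and 2707 lower in both, where list sizes alone give 742 and 920. Ribosomal RNA genes took 11.4% to 39.8% of neural reads, and 11.8% to 13.6% in the libraries labelled Kansl3 nKO, below the 16.5% to 29.5% of Cre controls.

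**Figure D3:**
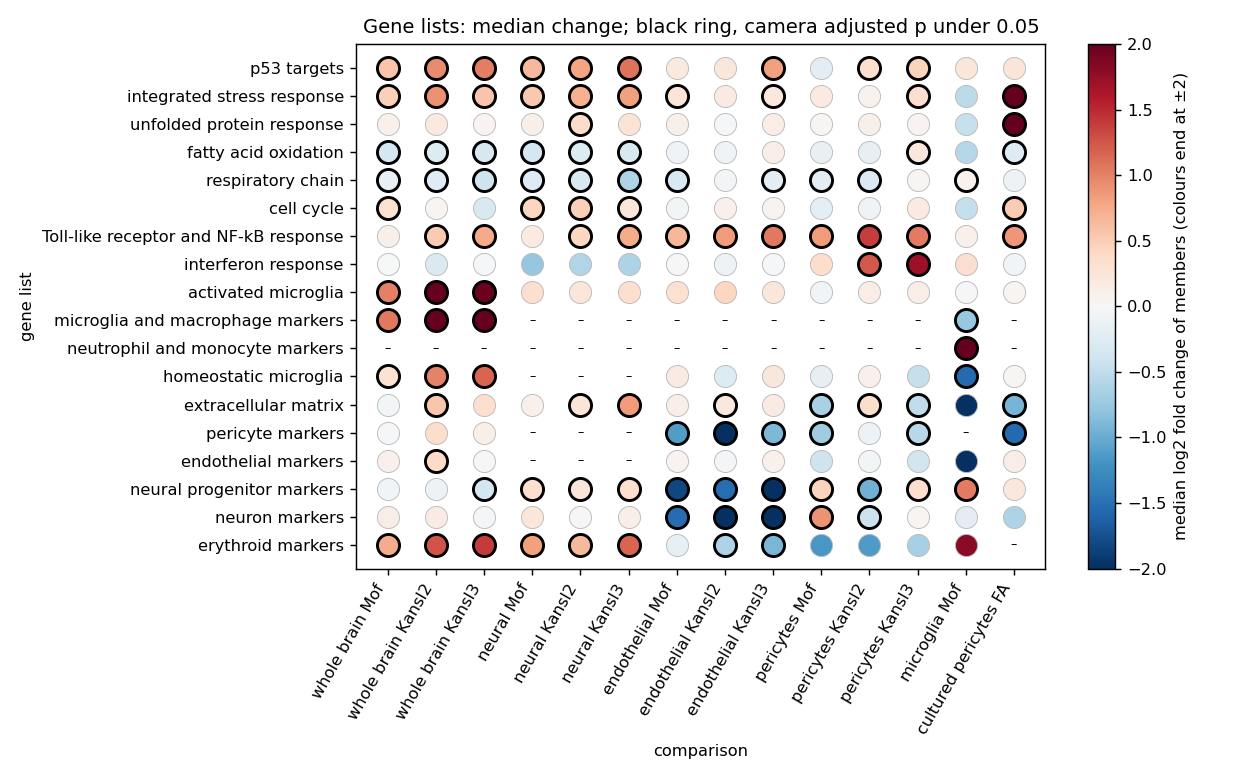
Median log2 fold change of the members of 18 gene lists (vertical axis) in each comparison (horizontal axis), shown as color from -2 to 2 against the Cre or vehicle control; each circle is a list with at least 5 members tested, and a black ring marks camera adjusted p under 0.05 with the preset correlation. Medians of p53 targets run from 0.56 to 1.09 in whole brain and neural cells.

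Did endothelial cells, which form the vessel lining, change when the knockout was in neural cells? No gene passed in any of the 3 endothelial comparisons with limma, so all values here are of lists. Toll-like receptor and NF-kB genes stood higher as a list, with medians of 0.67 under Mof, 0.84 under the Kansl2 label and 1.05 under the Kansl3 label, and 17 of 21, 17 of 21 and 21 of 22 members above 0. Camera gave adjusted p = 9.65e-06, 6.91e-06 and 9.72e-10 for the list, and adjusted p = 0.0488, 0.061 and 0.0192 with an estimated correlation, so that it passed under either correlation for Mof and Kansl3. Irf1, an interferon regulatory transcription factor, stood at 2.47 ± 0.45, 2.81 ± 0.48 and 2.92 ± 0.42 in these comparisons (adjusted p = 0.261, 0.384 and 0.105), and the adhesion molecule Icam1 stood at 1.31 ± 0.21, 1.04 ± 0.27 and 1.46 ± 0.23. Adjusted over the list alone, 3, 2 and 7 members rose.

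Markers of neighboring cell types stood lower as lists in endothelial libraries from knockouts, with no member passing. Pericyte markers had medians of -1.11, -2.17 and -0.90 under Mof, Kansl2 and Kansl3 (camera adjusted p = 0.00464, 4.38e-10 and 0.000289, and adjusted p = 0.482, 0.061 and 0.0861 with an estimated correlation). Their share of reads was 0.0407 ± 0.00383% in Cre controls (n = 4) and 0.0116 ± 0.00689% in libraries labelled Kansl2 nKO (n = 3). Neuron markers had medians of -1.54, -2.43 and -2.09 (camera adjusted p = 7.87e-07, 4.38e-10 and 1.39e-09, and adjusted p = 0.173, 0.0965 and 0.189 with an estimated correlation), with Tubb3 at -1.78 ± 0.34, -2.06 ± 0.42 and -2.86 ± 0.78. Neural progenitor markers had medians of -1.83, -1.53 and -2.14 (camera adjusted p = 9.65e-06, 6.91e-06 and 1.7e-06, and adjusted p = 0.0758, 0.061 and 0.0787 with an estimated correlation). Their summed share of reads hardly moved, from 0.148 ± 0.0122% in Cre controls to 0.138 ± 0.0141%, 0.163 ± 0.0642% and 0.136 ± 0.00988%. Endothelial markers themselves were not called, with medians of 0.06, -0.03 and 0.10 (camera adjusted p = 0.997, 0.825 and 0.865). Blood-brain barrier genes, the junction and transporter genes of brain endothelium, were called under the Kansl2 label alone (median -0.26, camera adjusted p = 0.00372, adjusted p = 0.407 with an estimated correlation), with the lipid transporter Mfsd2a at -1.01 ± 0.26.

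Among 17152, 16649 and 16466 genes tested for Mof, Kansl2 and Kansl3 (n = 4 against 4, 3 against 4 and 3 against 4), limma called 0, with 1482, 975 and 1055 at an unadjusted p under 0.05. The quasi-likelihood test of edgeR on recovered reads also called 0, while DESeq2 called 341, 159 and 219, the totals in the authors' deposited tables. On simulated endothelial data limma found 33.3%, 36.4% and 47.0% of genes changed 4-fold. Without Cre130, which had a mitochondrial share of 7.69%, 16 genes passed under the Kansl3 label. All 3 comparisons share 4 Cre libraries: fold changes correlated across genes at r = 0.722, 0.655 and 0.670 for Mof with Kansl2, Mof with Kansl3 and Kansl2 with Kansl3 (simulated 0.457, 0.457 and 0.424), and at a mean of 0.197, 0.139 and 0.157 over 6 splits that gave each knockout its own controls.

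Pericytes wrap small vessels and were sorted from the same stage. In Mof nKO no gene passed, and these libraries were poorer than Cre controls: ribosomal RNA genes took 2.69% to 4.73% of reads against 1.86% to 2.41%, and the mitochondrial share was 7.84 ± 2.87% against 5.14 ± 0.614%. They held a mean of 18892 detected genes against 20508, and M_577 had 11.1% mitochondrial reads and 1572515 reads in all. All 10 pericyte markers were below 0, with a median of -0.71 (camera adjusted p = 4.35e-10, adjusted p = 0.454 with an estimated correlation), and with Higd1b at -1.27 ± 0.18 (adjusted p = 0.0585), Vtn at -0.82 ± 0.16 and Pdgfrb, the receptor that recruits pericytes, at -0.71 ± 0.18. Their share of reads was 0.750 ± 0.138% in Mof nKO (n = 3) and 1.26 ± 0.156% in Cre controls (n = 4). Extracellular matrix genes had a median of -0.65, with the nidogens Nid1 at -1.34 ± 0.23 and Nid2 at -1.46 ± 0.26 (camera adjusted p = 1.83e-09, adjusted p = 0.454 with an estimated correlation). Toll-like receptor and NF-kB genes had a median of 0.84, with the chemokines Cxcl1 at 2.69 ± 0.36 (adjusted p = 0.0585) and Ccl2 at 2.54 ± 0.40 (camera adjusted p = 4.22e-06, adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone, 9 pericyte markers and 15 matrix genes fell and 6 NF-kB genes rose. Neuron markers were higher at the same time, with a median of 0.90 and Tubb3 at 1.17 ± 0.28 (camera adjusted p = 6.55e-05, adjusted p = 0.454 with an estimated correlation). Limma called 0 of 14112 genes, with 1888 at an unadjusted p under 0.05 (n = 3 against 4); edgeR called 9 and DESeq2 252, and the authors' deposited table holds 256. The limma count was 194 without M_586 and 2 without Cre_141.

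Among pericyte libraries labelled Kansl2 nKO, K2_328 held 18224 detected genes and 7.84% mitochondrial reads, against at least 19864 genes and at most 5.88% in Cre controls. In this group Cxcl1, a neutrophil-attracting chemokine, rose from 46.8 ± 14.6 to 372 ± 104 normalized counts (log2 fold change 2.98 ± 0.33, adjusted p = 0.00056), Icam1 from 35.4 ± 14.9 to 298 ± 97.0 (3.09 ± 0.39, adjusted p = 0.000876). Casp4, the caspase that senses intracellular lipopolysaccharide, rose from 0.156 ± 0.312 to 135 ± 59.3 (6.80 ± 0.85, adjusted p = 0.000876; 3 of the 4 controls listed at 0). The guanylate-binding gene Gbp7 rose by 2.83 ± 0.46 and the transcription factor Runx1 by 3.31 ± 0.48. Veph1 fell from 95.7 ± 23.8 to 7.96 ± 5.09 (-3.57 ± 0.53, adjusted p = 0.00207). Nell2, a secreted neuronal glycoprotein, fell by 3.13 ± 0.43 on the log2 scale, and Mt3, the brain metallothionein, fell from 357 ± 101 to 59.8 ± 44.3 (-2.75 ± 0.38, adjusted p = 0.00137).

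Of 20 Toll-like receptor and NF-kB genes 9 rose (15 up and 1 down adjusted over the list alone), with Ccl2 at 2.78 ± 0.34 and Nfkbia at 1.32 ± 0.18. Of 17 interferon response genes 3 rose (11 adjusted over the list alone), with Ifit1 at 5.33 ± 1.03 and Bst2 at 1.31 ± 0.29. Of 22 cholesterol synthesis genes 1 fell (9 adjusted over the list alone): Hmgcs1, the synthase before the rate-limiting step, at -1.40 ± 0.16. These lists passed under either correlation (camera adjusted p = 1.4e-13, 3.9e-09 and 2.06e-06, and adjusted p = 0.0273 with an estimated correlation for each). Neural progenitor markers had 6 of 14 down (7 adjusted over the list alone), with Hes5 at -2.50 ± 0.27 and Fabp7 at -1.64 ± 0.22 (camera adjusted p = 5.98e-08, adjusted p = 0.136 with an estimated correlation). Their share of reads was 0.218 ± 0.0229% against 0.411 ± 0.0609% in Cre controls. Glycolysis genes had 3 of 17 down (10 adjusted over the list alone), with Eno1 at -0.58 ± 0.12 (camera adjusted p = 0.00128, adjusted p = 0.19 with an estimated correlation). Limma called 137 genes higher and 181 lower of 14402 (n = 3 against 4), and DESeq2 called 793, where the authors' deposited table holds 770. The limma count was 110 without Cre_142 and 205 without K2_330, and between these without any one of Cre_134, Cre_139, Cre_141 and K2_338.

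Pericyte libraries labelled Kansl3 nKO held a mean of 18994 detected genes against 20508 in Cre controls. K3_327, K3_335 and K3_339 held 17760 to 18949 genes and 6.53% to 7.26% mitochondrial reads, against at least 19864 genes and at most 5.88% in Cre controls. In this group Ifit1, an antiviral gene, rose from 0.243 ± 0.485 to 118.7 ± 42.5 normalized counts (6.56 ± 0.70, adjusted p = 0.000716; 3 of the 4 controls listed at 0). Ifit3 rose from 12.97 ± 7.70 to 138.5 ± 102 (adjusted p = 0.012) and the interferon-induced GTPase Iigp1 from 1.23 ± 1.44 to 114 ± 75.2 (5.66 ± 0.79). Serpina3g, a protease inhibitor, rose to 101 ± 97.2 and was listed at 0 in every control. Hapln3, a matrix link protein, fell from 88.4 ± 33.1 to 14.1 ± 11.9 (-2.80 ± 0.57). Acox3, a peroxisomal fatty acid oxidase, fell from 110 ± 36.1 to 30.4 ± 23.0 (-2.10 ± 0.53, adjusted p = 0.0463).

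Of 19 interferon response genes 7 rose (12 adjusted over the list alone) and all 19 stood above 0, with Isg15 at 1.82 ± 0.34 and Bst2 at 1.32 ± 0.28 (camera adjusted p = 1.58e-12, adjusted p = 0.0875 with an estimated correlation). Of 19 Toll-like receptor and NF-kB genes 6 rose (9 adjusted over the list alone), with Ccl2 at 2.70 ± 0.32, Cxcl1 at 2.68 ± 0.32 and Icam1 at 2.41 ± 0.35 (camera adjusted p = 2.88e-09, adjusted p = 0.0875 with an estimated correlation). Pericyte markers had 3 of 10 down (8 down and 1 up adjusted over the list alone), with Cspg4, also called NG2, at -0.99 ± 0.14, Pdgfrb at -0.87 ± 0.13 and Notch3 at -0.99 ± 0.20 (camera adjusted p = 1.36e-05, adjusted p = 0.188 with an estimated correlation). Their summed share of reads was 1.19 ± 0.193% against 1.26 ± 0.156% in Cre controls, within the spread of the libraries. Shares of other marker lists differed at the same time. Neural progenitor markers held 0.566 ± 0.0900% against 0.411 ± 0.0609%, with Fabp7 up by 0.74 ± 0.16, and fibroblast markers 0.0395 ± 0.00732% against 0.0752 ± 0.0216%. Sorted neural cells of Cre controls held only 0.157 ± 0.0148% in progenitor markers, so that share cannot be turned into an amount of neural cells. Neuron markers held 0.0551 ± 0.0170% against 0.0439 ± 0.00906%, with overlapping libraries. In pericytes labelled Kansl2 nKO, where progenitor markers were lower, neuron markers held 0.0278 ± 0.00496%. A difference in RNA from neural cells is therefore not excluded. Extracellular matrix genes had 8 of 33 down and 1 up (12 down and 3 up adjusted over the list alone), with the basement membrane genes Col4a1 at -0.99 ± 0.14 and Hspg2 at -1.46 ± 0.24 (camera adjusted p = 0.000175, adjusted p = 0.351 with an estimated correlation). Of 23 p53 targets 5 rose (8 adjusted over the list alone), with Ccng1 at 1.46 ± 0.24 (camera adjusted p = 0.000179, adjusted p = 0.0875 with an estimated correlation). Limma called 269 genes higher and 177 lower of 14325 (n = 4 per group), and DESeq2 called 1195, where the authors' deposited table holds 1154. The limma count was 175, 150, 295 and 176 without Cre_134, Cre_139, Cre_141 and Cre_142, and 256 and 238 without K3_327 and K3_339.

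**Figure D4:**
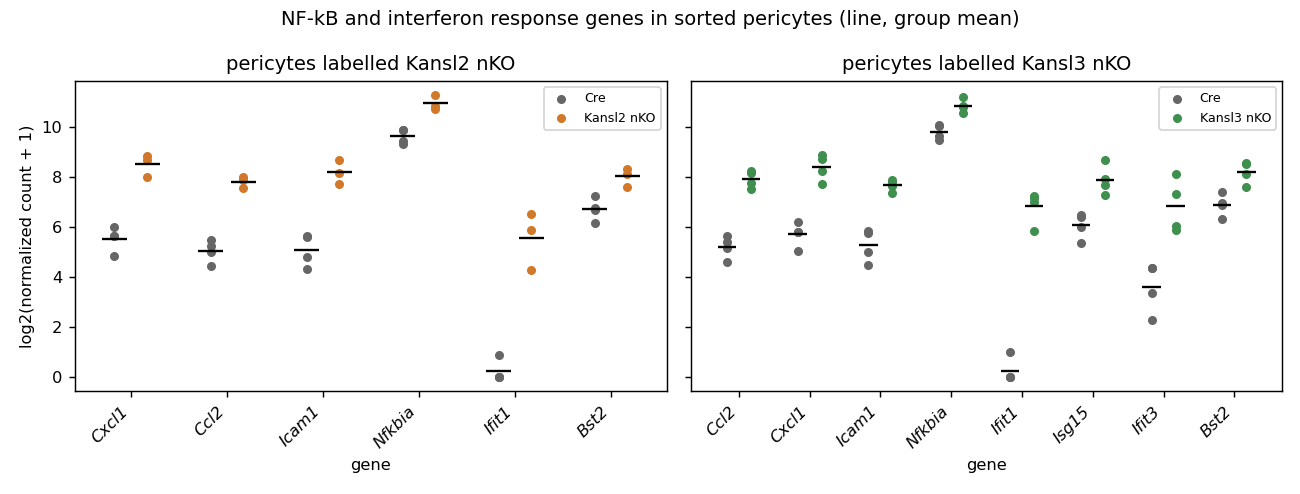
Normalized counts on the log2(value + 1) scale (vertical axis) of NF-kB and interferon response genes (horizontal axis) in sorted pericytes labelled Kansl2 nKO (n = 3, left) and Kansl3 nKO (n = 4, right) and their Cre controls (n = 4, grey); each point is a library and lines are group means. Cxcl1 stands 2.98 ± 0.33 (left) and 2.68 ± 0.32 (right) above its controls.

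Pericyte fold changes correlated across genes at r = 0.204 for Mof with Kansl2, 0.444 for Mof with Kansl3 and 0.116 for Kansl2 with Kansl3, where shared controls alone gave 0.421, 0.452 and 0.450 in simulations. With separate controls the means over 6 splits were 0.0102, 0.202 and -0.0715. Kansl2 and Kansl3 shared 25 higher and 2 lower genes, where list sizes give 2.52 and 2.32, and 17 genes were called in opposite directions.

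Microglia of Mof nKO were compared with Cre controls (n = 3 per group), and the knockout libraries were poorer. They held 12325 to 15446 detected genes against 17454 to 19055, and a mitochondrial share of 12.4 ± 5.97% against 5.71 ± 1.12%. The median log2 fold change of all 13141 genes was -0.50, and changes are best read against it. Homeostatic microglia genes, the resting signature, had a median of -1.56 with all 12 below 0, among them Siglech at -3.39 ± 0.57, Sall1 at -5.46 ± 1.63 and Fcrls at -1.54 ± 0.35 (adjusted p = 0.188, 0.267 and 0.188; for the list camera adjusted p = 1.65e-05, adjusted p = 0.499 with an estimated correlation). Neutrophil and monocyte markers stood higher, with a median of 3.12 over 6 genes, the calprotectin gene S100a8 at 3.93 ± 0.65 (camera adjusted p = 2.98e-06, adjusted p = 0.225 with an estimated correlation). Adjusted over the list alone, 5 homeostatic genes fell and 4 monocyte genes rose. Microglia and macrophage markers held 0.570 ± 0.1999% of reads against 1.32 ± 0.169% in controls. Limma called 0 genes, with 1341 at an unadjusted p under 0.05, edgeR 0 and DESeq2 735, the total in the authors' deposited table. On simulated data of this kind limma found 3.03% of genes changed 4-fold. The limma count was 849 without M643 and 1 without M689, and 825 without M646 and M689 together, a setting added after seeing the data.

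Do pericytes respond to fatty acids themselves? Primary pericytes of adult brain were given C14:0 and C16:0 (200 µM each), C20:0 (20 µM) and C24:0 (10 µM), or vehicle. Cxcl2, a neutrophil-attracting chemokine, rose from 3.77 ± 0.364 to 430 ± 92.8 normalized counts (log2 fold change 6.79 ± 0.27, adjusted p = 2.29e-06). Fgf21, a stress-induced hormone, rose from 1.86 ± 0.927 to 129 ± 57.7 (6.01 ± 0.52) and the endothelin receptor Ednrb from 4.03 ± 0.859 to 240 ± 42.2 (5.85 ± 0.27). The sterol exporter Abcg1 fell from 2993 ± 79.7 to 23.6 ± 13.5 (-6.98 ± 0.30, adjusted p = 2.72e-06), elastin (Eln) fell from 3514 ± 620 to 29.3 ± 6.14 (-6.90 ± 0.20) and the water channel Aqp4 from 234 ± 32.0 to 4.68 ± 5.36 (-5.61 ± 0.47). With edgeR 5046 genes rose and 5358 fell among 15625 (n = 3 per group), and the authors' deposited table holds 10627. Fatty acid library 1 stood apart from libraries 2 and 3. It held 0.883% mitochondrial reads against 1.48% and 1.38%, and 22261 detected genes against 22953 and 23117. Without it 11945 genes changed.

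All 22 integrated stress response genes rose, with Slc7a11, the cystine transporter, at 4.17 ± 0.16, Shmt2 at 2.95 ± 0.11 and Atf3 at 2.96 ± 0.11 (camera adjusted p = 3.94e-10, adjusted p = 0.699 with an estimated correlation). All 16 unfolded protein response genes rose, with the chaperone Hspa5 at 4.08 ± 0.13 and Dnajb9 at 3.17 ± 0.08 (camera adjusted p = 1.84e-09, adjusted p = 0.618 with an estimated correlation). Toll-like receptor and NF-kB genes had 19 of 26 up and 3 down, with Ptgs2, the inducible cyclooxygenase, at 4.50 ± 0.12, Cxcl10 at 4.61 ± 0.14 and Cxcl1 at 3.30 ± 0.11 (camera adjusted p = 0.000228, adjusted p = 0.699 with an estimated correlation). Extracellular matrix genes had 26 of 33 down and 4 up (26 down and 5 up adjusted over the list alone), with Col3a1 at -3.66 ± 0.12 and Col1a1 at -3.10 ± 0.13 (camera adjusted p = 0.000111, adjusted p = 0.913 with an estimated correlation). Pericyte markers had 5 of 6 down and 1 up, with Pdgfrb at -3.00 ± 0.13 and Notch3 at -1.95 ± 0.08 (camera adjusted p = 0.0445, adjusted p = 0.618 with an estimated correlation). These markers held only 0.0218 ± 0.000705% of reads with vehicle and 0.00356 ± 0.000271% with fatty acids, where sorted pericytes of Cre controls held 1.26 ± 0.156%. Fibroblast markers, at 0.0668 ± 0.000324% with vehicle and 0.0145 ± 0.00187% with fatty acids, had 5 of 6 down (camera adjusted p = 0.0121, adjusted p = 0.894 with an estimated correlation), so the fall was not limited to pericyte markers. Fatty acid oxidation genes had 12 of 27 down and 2 up, with Acadm at -2.49 ± 0.15 and Acadl at 1.48 ± 0.06 (camera adjusted p = 0.0312, adjusted p = 0.913 with an estimated correlation). PPAR targets, genes switched on by fatty acids through nuclear receptors, went both ways, 7 of 16 up and 5 down, with Acot2 at 3.56 ± 0.15, the lipid droplet coat Plin2 at 3.03 ± 0.18 and Angptl4 at 1.99 ± 0.21 among those up (camera adjusted p = 0.515).

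**Figure D5:**
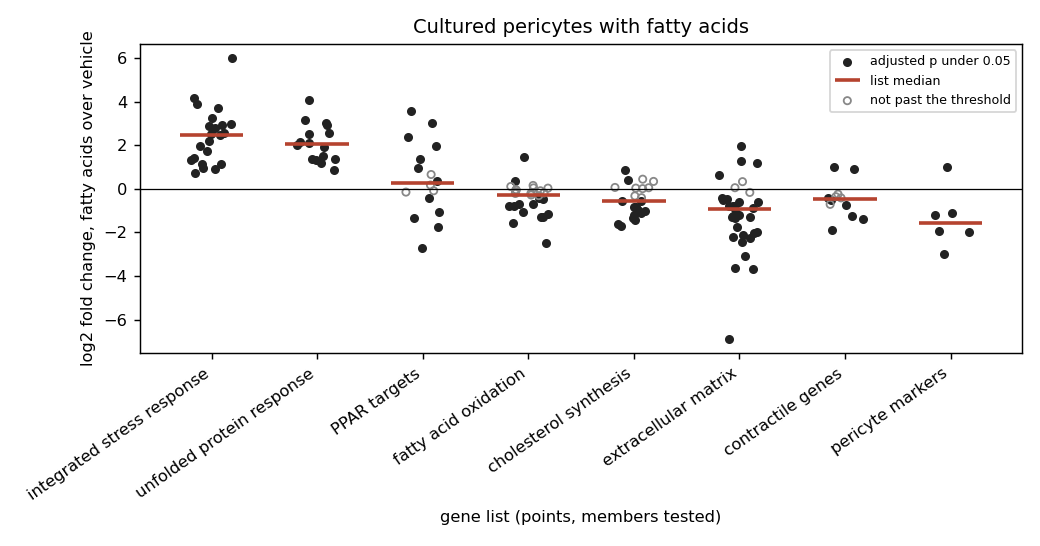
Log2 fold change of fatty acids over vehicle (vertical axis) for the members of 8 gene lists (horizontal axis) in cultured pericytes (n = 3 per group); each point is a gene, filled at adjusted p under 0.05, and lines are list medians. The medians are 2.50 for the integrated stress response, 2.07 for the unfolded protein response and -0.94 for the extracellular matrix.

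Of 352 list tests, camera called 82 up and 52 down with its preset correlation, and 8 of them held with an estimated correlation. Those 8 were p53 targets and activated microglia in whole brains labelled Kansl2 nKO, the integrated stress response in Mof neural cells, NF-kB genes in Mof and Kansl3 endothelial cells, and NF-kB, interferon and cholesterol genes in pericytes labelled Kansl2 nKO. The self-contained test fry called 120.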

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

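Single libraries stood apart in 10 of 126 tests, each of a measure within a group, where chance alone gives about 1 in 20, or 6.3. Only groups of 4 libraries were tested: endothelial Cre controls and Mof nKO, and pericyte Cre controls and those labelled Kansl3 nKO. Groups of 3, which include all of whole brain, neural cells, microglia and cultures, were not screened. Many tests used the same libraries, and all 10 flags fell in endothelial and pericyte Cre controls. Endothelial Cre94 had 25260285 reads, where the other controls had 12472524 or fewer. Endothelial Cre130 had a mitochondrial share of 7.69%, against 1.11% to 2.18%. The same library had the highest pericyte marker score, at 0.681, 0.682 and 0.688 in the Mof, Kansl2 and Kansl3 tables, and the lowest blood-brain barrier score, at -0.402 in the Kansl2 table. Pericyte Cre_142 held 126 Kat8 counts against 42.3 to 47.0 in the other controls, and 90.5 Kansl2 counts against 128 to 133. Casp4 stood at 0.6246 in pericyte Cre_134 and Ifit1 at 0.971 in pericyte Cre_139, with the other controls at 0.

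Some lists moved one way in every knockout library of one tissue and the opposite way in another tissue, and these differences were not tested. Under Mof, homeostatic microglia genes had a median of 0.30 in whole brain and -1.56 in sorted microglia, and microglia and macrophage markers 1.06 and -0.75. Under Mof, the respiratory chain was at -0.26, -0.32 and -0.21 in neural cells, endothelial cells and pericytes and at 0.0832 in microglia, where the sign turned with TMM scaling or without Cre203 and the median of all genes was -0.50. Glycolysis stood at 0.34 in neural and -0.13 in endothelial cells, and neural progenitor markers at 0.34 in neural cells, -1.83 in endothelial cells and 0.46 in pericytes. Under the Kansl2 label, glycolysis was at 0.28 in neural cells, -0.24 in endothelial cells and -0.39 in pericytes. Progenitor markers were at 0.26, -1.53 and -0.96 in those tissues, and blood-brain barrier genes at 0.36 in neural and -0.26 in endothelial cells. Under the Kansl3 label, progenitor markers were at -0.37 in whole brain, 0.33 in neural cells, -2.14 in endothelial cells and 0.33 in pericytes. Fatty acid oxidation was at -0.33 in whole brain, -0.31 in neural cells and 0.22 in pericytes. Extracellular matrix genes were at 0.85 in neural cells and -0.51 in pericytes, and angiogenesis genes at 0.54 and -0.62.

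Are the libraries labelled Kansl2 nKO and Kansl3 nKO what the labels say, given that Kansl2 and Kansl3 were not lower in them? These tests were chosen after the results were seen. At least 4332 genes differed from Cre, where other splits gave at most 5. Between Mof nKO and those labelled Kansl3 nKO 2196 genes differed (702 or more with a library left out), where other splits gave 0. Both passed the bound set, but each rests on only 10 splits, too few by themselves to exclude chance. Such counts cannot tell genotype from a litter or batch that the labels do not give, so alone they exclude neither identity. Kat8 fell and p53 targets rose under both labels in whole brain and neural cells alike, which makes Cre controls unlikely. Whether those labelled Kansl2 nKO are Mof nKO could not be told by this test: 1409 genes differed where another split gave 530, but 439 without K2_63. The 439 comes from a fit with fewer libraries than the 530, so the counts are not directly comparable. Kat8 fell in both, but by less under the Kansl2 label than under Mof, most clearly in neural cells. An exchange of the Kansl2 and Kansl3 labels could not be told, as Kansl2 stood at 0.44 in whole brains labelled Kansl3 nKO. A deletion that leaves most of the transcript is a possible explanation that could not be told either, as the whole gene stood at 0.46 under the Kansl2 label and exons are not in the tables.

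Do NF-kB and interferon genes in pericytes come from other cells or from depth? Predictions for these tests were written before their results. The rise of source markers accounted for at most 0.306% of the rise through RNA from microglia, 0.224% through endothelial cells and 0.738% through neural cells. The bound was 10 percent. Levels in the source were those of Cre controls, so these 3 cell types are unlikely as the source at control expression. Cells of these types that express more of these genes, or fewer of the markers, in knockout brains were not tested. Fibroblasts, neutrophils, monocytes and other cells were not tested. Depth is unlikely too: with every library thinned to the lowest total, the highest adjusted p of the lists was 7.04e-09. A response of pericytes to knockout neural cells may remain, but no test here separates it from other causes.

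Do microglia genes in whole brains labelled Kansl2 nKO and Kansl3 nKO reflect more microglia or blood, the last test chosen after the results were seen? With more microglia and unchanged expression, genes found in microglia alone could share a single fold. Here "alone" means against sorted neural cells, endothelial cells and pericytes. Other myeloid cells were not sorted, so the genes may be theirs too. Of 76 such genes 69 and 73 rose under the Kansl2 and Kansl3 labels (medians 2.57 and 2.50). They ran from Clec7a at 5.57 and 5.79 and Csf1r at 1.27 and 1.42 to P2ry12 at -0.42 ± 0.32 and -0.05 ± 0.31. Single genes were not used to decide. The interquartile range of the 76 genes was 1.996 and 2.194 times that from their errors. The bound was over 2 in both, so by that bound this could not be told. Under both labels the spread of the set was still wider than its errors give. For these genes it argues against a single shared fold, and so against more microglia with unchanged expression as the only cause. More microglia together with changed expression could not be told. Nor could other myeloid cells that rose by folds of their own, which would widen the spread without changed expression. Neutrophil and monocyte markers held 0.00218% and 0.00219% of reads under the Kansl2 and Kansl3 labels, against 0.000168% in Cre controls. Blood left in the tissue could not be told either: summed erythroid markers reached 3.99-fold in a library, with means of 2.40 and 2.60 against 4.13 and 3.90 for microglia markers.

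Relabelling the same libraries in every other way, with predictions written before the results, showed how often chance may give as many calls. In pericytes 1 of 35 splits, the real one, reached 318 genes under the Kansl2 label (highest other 6) and 446 under Kansl3 (highest other 1), so chance is an unlikely source there. With 0 genes called, 35 of 35 splits reached the real count in endothelial cells (each of 3 comparisons) and in Mof pericytes, where another split gave 5. Any split reaches a count of 0, so this outcome was fixed in advance and tests nothing. For lists, as many were called in 5, 2 and 2 of 35 splits in endothelial cells (real 7, 9 and 9, highest other 12, 10 and 10). In pericytes the lists reached the real 8, 10 and 11 in 8, 5 and 3 of 35 splits (highest other 10, 13 and 12), so the number of lists called could come from chance.

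Groups of 3 allow only 10 splits, too few to exclude chance, and 1 of 10, the real one, reached the count of genes in whole brain, neural cells, cultures and between knockouts. Real counts in whole brain were 972, 4332 and 5543 (highest other 0 in each), and in neural cells 5011, 5864 and 8023 (highest other 0, 5 and 0). Cultures gave 10404 (highest other 0), and 1409, 2196 and 6 genes differed between knockouts (highest other 530, 0 and 1). In microglia 10 of 10 splits reached the real 0, as any split must, so this tests nothing. Lists reached the real number in 1, 6 and 5 of 10 splits in whole brain (real 9, 13 and 11, highest other 8, 20 and 14) and in 1, 1 and 4 in neural cells (real 8, 13 and 12, highest other 7, 12 and 12). In microglia 2 of 10 splits reached 5 lists (highest other 5), and in cultures 5 of 10 reached 9 (highest other 12).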

How the results depend on the processing

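Of gene values under all settings, 17282 kept their size, 602 were weaker, 274 stronger, 180 moved and 0 reversed; of list medians 4274 kept theirs, 223 moved and 3 reversed. The median of erythroid markers in endothelial cells under the Kansl3 label ranged from -1.45 to 0.0326 with a library left out (the latter without K3-257). The same happened to another list median: respiratory chain in microglia Mof nKO became -0.0901 with TMM scaling, and ranged from -0.0679 (without Cre203) to 0.288 with a library left out. For these the cause was not tested. Of the lists called, 8 held with an estimated correlation. The estimate was above the preset value for some lists and below it for others. Fatty acid oxidation in neural cells under Mof and the Kansl2 label had an estimate below the preset value, and still lost its call. Under Mof the estimate was 0.000374, and the unadjusted camera p went from 0.000448 to 0.0172. Correlation between genes therefore does not account for every lost call. Camera with an estimated correlation also uses fewer degrees of freedom, which raises p at the same correlation. How many calls were lost through either was not tested.

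Genes changed in whole brain under Mof numbered 1636 with no filter (52.7% higher), where more genes were tested, and the share of genes higher was 40.9% with only the 6 libraries, against 32.3%. Between Kansl2 and Kansl3 the 6 genes became 97 with DESeq2 (62.9% higher) and 848 with no filter (57.3% higher). In endothelial cells under Mof the 0 became 1 with a pseudocount of 8, 1 with a mean of at least 1, 1 with at least 50, 341 with DESeq2 and 151 with array weights. Under the Kansl2 label it became 159 with DESeq2 and 54 with array weights. Under the Kansl3 label it became 2, 1 and 2 with the pseudocount and the 2 means, 219 with DESeq2, 42 with array weights, and 12 with edgeR without Cre130. In pericytes under Mof the 0 became 11, 12 and 13 with the pseudocount and the means, 9 with edgeR, 252 with DESeq2 and 4 with array weights. DESeq2 gave 793 and 1195 under the Kansl2 and Kansl3 labels. In microglia the 0 became 735 with DESeq2 and 825 without M646 and M689, where the lone knockout library left is assumed to vary like the controls. Array weights and the settings without those libraries were chosen after seeing the data. For each of these counts the cause was not tested.

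With each library left out in turn, changed genes ranged over 170 to 1253, 2843 to 4153 and 3638 to 5254 in whole brain (Mof, Kansl2, Kansl3), 3669 to 4959, 4382 to 5875 and 6856 to 8702 in neural cells, 0 to 0, 0 to 0 and 0 to 16 in endothelial cells, 0 to 194, 110 to 353 and 150 to 495 in pericytes, 0 to 849 in microglia and 9066 to 11945 in cultures. Between knockouts they ranged over 439 to 1793 (Mof and Kansl2), 702 to 1924 (Mof and Kansl3) and 2 to 1041 (Kansl2 and Kansl3). Fewer libraries change the power, and no other cause was tested.

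In microglia the median log2 fold change of all genes was -0.50, and became -0.66 with TMM, -0.01 with edgeR, 0.18 with DESeq2, -0.26 with a pseudocount of 8, -0.32 with a mean of at least 50, -0.31 with array weights and 0.06 without M646 and M689. No gene changed 2-fold was found in simulated data of this set.

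Treating equal replicate numbers in cultures as a block gave 10458 genes, 4975 higher and 5483 lower, with 10052 of the calls kept. Same-number libraries correlated at 0.223, 0.148 and 0.0477, and vehicle 3 correlated best with fatty acid library 2 (0.169), so the pairing is a hint from the data, not the design.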

Other observations

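Dlx1, a transcription factor of inhibitory neurons, fell by 1.41 ± 0.23 in whole brains labelled Kansl2 nKO and by 1.27 ± 0.23 in those labelled Kansl3 nKO (adjusted p = 0.000488 and 0.00095), and did not pass in those of Mof nKO (-0.63 ± 0.22, adjusted p = 0.0972). In neural cells Dlx1 fell by 1.69 ± 0.10, 1.56 ± 0.12 and 1.45 ± 0.09 under Mof, Kansl2 and Kansl3. The neuron list went both ways in neural cells (camera adjusted p = 0.0787, 0.723 and 0.71). In neural cells Pdgfra fell by 1.99 ± 0.30, 1.94 ± 0.30 and 1.56 ± 0.28. Interferon response genes had 3 of 5, 4 of 6 and 4 of 6 members down in neural cells, with Ifit2 at -0.82 ± 0.20, -1.07 ± 0.20 and -1.26 ± 0.18 (camera adjusted p = 0.0607, 0.0749 and 0.0965).

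Fibroblast markers had 4 of 7 up and 1 down in whole brains labelled Kansl2 nKO, with the collagens Col3a1 at 2.86 ± 0.84 and Col1a1 at 2.38 ± 0.72 (camera adjusted p = 0.211). Choroid plexus markers had too few members for a list test; there Ttr, the transthyretin of choroid plexus, rose by 6.79 ± 1.93. Both rises were uneven: fibroblast markers held 0.00219% to 0.0224% of reads in these 3 libraries against 0.00246% to 0.00298% in Cre controls, and choroid plexus markers 0.00376% to 0.0369% against 0.00359% to 0.00489%. Contractile genes had 2 of 7 up in the same brains, with Tagln at 1.54 ± 0.47 (camera adjusted p = 0.211), and hypoxia response genes had 1 of 14 up, Ddit4 at 0.85 ± 0.19 (camera adjusted p = 0.472). In pericytes labelled Kansl3 nKO angiogenesis genes had 3 of 15 down (4 adjusted over the list alone), with Notch1 at -0.81 ± 0.15 and Unc5b at -1.17 ± 0.22 (camera adjusted p = 0.00112, adjusted p = 0.0875 with an estimated correlation).

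Among other NSL members, in neural cells labelled Kansl3 nKO Kansl1 rose by 0.75 ± 0.08 and Mcrs1 fell by 0.50 ± 0.08 (camera adjusted p = 0.411 for the NSL list). Of the MSL complex, the other assembly of MOF, Msl1 rose by 0.36 ± 0.07 and Msl2 by 0.25 ± 0.07 in Mof neural cells, too few members for a list test. Fatty acids raised 6 of 9 NSL genes in cultured pericytes (7 adjusted over the list alone), with Wdr5 at 1.28 ± 0.08, Kansl2 at 1.15 ± 0.08 and Kat8 at 0.52 ± 0.07 (camera adjusted p = 0.0221, adjusted p = 0.618 with an estimated correlation).

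Xist and Ddx3y mark female and male tissue. In all 14 endothelial libraries Ddx3y stood above Xist, while Xist stood above in 16 of the 44 other embryonic libraries and in all 6 cultures. In microglia 2 of 3 Cre controls and 0 of 3 Mof nKO libraries had Xist above. Fold changes across genes, which are not independent replicates, correlated between whole brain and neural cells at Spearman 0.669, 0.746 and 0.711 under Mof, Kansl2 and Kansl3, and from -0.0700 to 0.239 for all other pairs of tissues.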
